A study of Homo sapiens with 4 samples.

How the data were processed

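RNA of HT-29 cells, an established human colorectal adenocarcinoma line, was hybridised to 4 two-colour Agilent whole-genome expression arrays. Per the labels, cells were grown in medium with 10% fetal serum, starved of serum for 16 h and then treated with sodium butyrate for 24 h or 48 h. The labels do not say whether the untreated cells were starved or how long they were cultured. Per the labels, 500 ng of each RNA was amplified, with Cy3 put into the cRNA of butyrate-treated cells and Cy5 into that of untreated cells. No array had the dyes swapped, so dye and treatment go together in each comparison with untreated cells.

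The files are scanner output of Agilent Feature Extraction 9.5.3.1, per the file headers. The deposited values used here are spot intensity values (mean signal and median local background in each channel). The deposited processed intensity values, background-subtracted and dye-normalized by that software per the file headers, served as an alternative. The deposited log10 ratio of Cy5 over Cy3 was used to check the direction. Its sign was turned, and it correlated across genes with the log2 ratios computed here at 0.88 to 0.95 on the 4 arrays. Further processing by the submitters is not given in the sources used here.

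Background was corrected with normexp and an offset of 50, and each array was normalized by loess with control spots at weight 0 (limma 3.58.1, R 4.3.3). Spots flagged as non-uniform or as population outliers were left out, and saturated spots were kept. Loess sets the typical ratio of each array to 0, so the values describe changes relative to the other genes. A log2 ratio is butyrate over untreated throughout. Of 41000 probes, 23845 were named by RefSeq accession, 2018 by current symbol and 966 by an older symbol through a table of assembly GRCh38.p14, and 14171 kept the name in the files. One file had been saved from a spreadsheet and 38 of its gene names differed, so names were taken from the first array. Probe positions are those of the files, on build hg17.

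A probe was tested if it was well above background in Cy3 on both arrays of a time point or in Cy5 on all 4 arrays. Cy3 needed 2 arrays and Cy5 needed 4, so dim genes could pass more easily when higher under butyrate. This gave 20281 probes. Each gene was represented by its brightest tested probe, leaving 15674 genes. Other tested probes of called genes had the same sign as the chosen one for 277 of 295 probes at 24 h and 469 of 493 at 48 h.

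The 4 arrays lay on 2 slides, each with 1 array of 24 h and 1 of 48 h. Replicate 1 of both time points lay on slide 1 and replicate 2 on slide 2. Per the labels, both arrays of slide 1 had the same untreated RNA. Those of slide 2 carry no number and were taken to share 1 untreated RNA. Normalized Cy5 log2 signals correlated at 0.995 and 0.999 within slides and at 0.921 on average between them, which a shared hybridisation can also give. A limma model with a coefficient for each time point was fitted to all 4 arrays with the slide as a random block. The routine of limma that estimates the within-slide correlation returned no value for 4 arrays and 2 coefficients. The same estimate was therefore written out per gene, and the consensus was 0.703. Tests were two-sided, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. The model had 2 residual and 6.93 prior degrees of freedom. The design text names 2 replicates of each kind. The number of arrays limits the precision.

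Of 34 gene lists fixed before the data were examined, 33 had 3 or more tested members and were tested with limma's cameraPR on the moderated statistics. The preset inter-gene correlation was 0.01, with adjustment over the lists of a comparison. The germline list had 2 tested members and was not tested. A second run used a correlation estimated per list, with estimates below 0 set to 0. It was 0 for the interferon, Paneth and secretory antimicrobial, neuron and endothelial lists and 0.007 for the goblet and apoptosis lists. These values lie below the preset 0.01, so for these lists the second run was the less strict test before adjustment. Named genes were the 10 largest rises and 10 largest falls at each time point among genes with adjusted p under 0.05, the same sign on both arrays, an approved symbol and both groups well above background. For 48 h versus 24 h the number was 5 each way. Up to 5 genes a direction below background in one group were given as bounds, or as the measured ratio where the bound equalled it. Up to 4 members of each list that passed or had a called member were eligible, and 12 genes were fixed in advance. Some genes that this rule names are not reported here.

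On simulated data for 15674 genes at 24 h, 32 of 50 genes changed by 1 on the log2 scale were called and 50 of 50 changed by 2. For 48 h versus 24 h, 22 of 25 genes changed by 1 were called and 2 of 25 changed by 0.5. Of the simulated calls, 16 of 198 were false at 24 h, 14 of 167 at 48 h and 11 of 85 for 48 h versus 24 h. Alternatives covered the background correction, the normalization, the detection filter, the choice of probe, the variance model, the slide block, each array left out, the list correlation and a 2-fold threshold. Leaving out probes saturated in Cy5 was added after the data were seen.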

Results

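The series measured gene expression in HT-29 cells after 24 h and 48 h of sodium butyrate, a short-chain fatty acid and histone deacetylase inhibitor, against untreated cells. There were 2 arrays per time point, each with its own butyrate-treated RNA in Cy3. The untreated RNA in Cy5 was taken to be shared by the 2 arrays of a slide. Of 43376 non-control spots, 49.7% to 55.6% were well above background in Cy3. In Cy5 the share was 39.5% and 41.0% on slide 1 and 63.3% and 63.8% on slide 2. The negative-control median in Cy5 was 435 and 420 on slide 1 and 59.6 and 57.6 on slide 2. Between 592 and 653 spots per array were saturated in Cy5 and at most 3 in Cy3. A saturated Cy5 spot understates the untreated level, so it makes a rise appear too large.

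The first comparison asks which genes differed after 24 h of butyrate. Genes of cell division fell together: 47 of 57 tested genes of the G2/M and mitosis list and 28 of 49 of the G1/S and DNA replication list were called lower, and none was called higher. TYMS, thymidylate synthase, fell by 3.88 on the log2 scale (SE 0.30, n = 2 arrays, 14.7-fold), and CDC45, a replication helicase factor, fell by 3.81 (SE 0.24, 14.0-fold). MMP7, the secreted protease matrilysin, fell by 3.65 (SE 0.36). Among genes eligible for naming, with both groups well above background, the largest rise was that of TEX19, a gene known from testis, at 3.98 (SE 0.26, 15.8-fold). It was followed by the ubiquitin ligase subunit FBXO2 at 3.62 (SE 0.26) and the chromatin remodelling subunit SMARCD3 at 3.62 (SE 0.29).

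Of 15674 genes, 538 were called higher and 418 lower at 24 h. All 956 had the same sign on both arrays. Of the genes called higher, 17 were well above background in Cy5 on no array and 119 on 1 to 3 arrays. Of those called lower, 20 were well above background in Cy3 on neither 24 h array. Without 24 h replicate 2 the counts were 126 and 127, and median centring without loess, which put the median of all genes at -0.66, gave 345 higher and 7021 lower. Among the genes eligible for naming, the other large rises were LGALS1 (galectin-1) at 3.49, KREMEN2 at 3.29, ALPG at 3.23 and NDRG4 at 3.18. Next came the adrenergic receptor ADRA2C at 3.12, the carboxypeptidase SCPEP1 at 3.02 and COX6B2 at 2.93. The adjusted p of these genes ran from 0.000609 for LGALS1 to 0.00264 for ALPG. ALPG is closely similar to other alkaline phosphatase genes, so its probe's signal is uncertain. The other large falls were PCLAF at -3.68, the cohesin regulator CDCA5 at -3.37, the kinetochore gene NDC80 at -3.24, the transcription factor gene MYB at -3.21, the condensin gene NCAPG at -3.19, the ubiquitin-conjugating enzyme gene UBE2C at -3.13 and HMMR at -3.11. The TEX19 probe lies on hg17 chromosome 17 at 77914834 to 77914893 and the TYMS probe on chromosome 18 at 663276 to 663335.

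Some genes were not well above background in one group. Their change is given as a bound or as a measured ratio, computed from channel signals and open to dye bias. DACT3 was at least 13.2-fold higher at 24 h. DSCC1 was at least 4.25-fold lower and MND1 at least 4.17-fold. For ARAP3, RIMS3 and RRM2, a ribonucleotide reductase subunit, the dim signal lay above the lowest signal among probes well above background. Their values are therefore measured ratios and not lower bounds: 4.52-fold higher for ARAP3, 4.51-fold higher for RIMS3 and 5.07-fold lower for RRM2. At 48 h, where the dim signal was raised to that lowest signal, the bounds were at least 3.69-fold for ARAP3, 4.43-fold for RIMS3 and 8.38-fold for RRM2.

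The G2/M list had a median of -1.82 at 24 h, -2.27 on slide 1 and -1.49 on slide 2 (adjusted p = 4.97e-73, and adjusted p = 7.76e-05 with an estimated correlation). Adjusted over the list alone, 53 of its genes were lower. The G1/S list had a median of -1.30, -1.21 on slide 1 and -1.22 on slide 2 (adjusted p = 1.42e-39, and adjusted p = 0.00566 with an estimated correlation), and 41 genes were lower when adjusted over the list alone. GINS2, of the replicative helicase, was at -2.06. In the ribosome biogenesis list 2 of 42 genes were called lower, NOP56 at -1.20 and GNL3 at -1.14. Its median was -0.39, -0.12 on slide 1 and -0.65 on slide 2 (adjusted p = 0.000321, but adjusted p = 0.551 with an estimated correlation).

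Among the lists that passed upward at 24 h, metallothioneins had 5 of 12 genes called higher, among them MT2A at 1.51 and MT1G at 1.23. These genes are near copies of one another, so the values of single members are uncertain. The list's median was 0.82, 0.71 on slide 1 and 0.99 on slide 2 (adjusted p = 3.97e-06, and adjusted p = 0.0141 with an estimated correlation), with 8 genes higher when adjusted over the list alone. The xenobiotic and glutathione list had 5 of 31 genes called higher, with CYP1A1 at 2.87, CYP1B1 at 2.07, TXNRD1 at 1.96 and the aryl hydrocarbon receptor gene AHR at 1.33 (adjusted p = 0.00042, and adjusted p = 0.0372 with an estimated correlation). The list's median was 0.59, 0.31 on slide 1 and 0.83 on slide 2, and 12 genes were higher and 2 lower when adjusted over the list alone. CYP1A1 was at 4.07 on slide 1 and 1.67 on slide 2. The fatty acid oxidation and ketogenesis list had 3 of 36 genes called higher, ACSL1 at 2.41, ACSL3 at 1.65 and ECI2 at 1.33, of which the first 2 activate fatty acids for several pathways. Its median was 0.31, 0.11 on slide 1 and 0.56 on slide 2 (adjusted p = 0.00518, but adjusted p = 0.546 with an estimated correlation).

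Other lists passed upward at 24 h with the preset correlation and not with an estimated one. In the actin cytoskeleton and keratin list 3 of 35 genes were called higher, the keratin gene KRT23 at 3.54 among them, and TPM2 was called lower at -1.30. Its median was 0.32, 0.05 on slide 1 and 0.54 on slide 2 (adjusted p = 0.0175, but adjusted p = 0.474 with an estimated correlation). The hypoxia list had P4HA1 at 1.66 and NDRG1 at 1.97 called higher, the latter saturated in Cy5 on 2 arrays, and CA9 called lower at -1.15 (adjusted p = 0.0275, but adjusted p = 0.551 with an estimated correlation). The glycolysis list had 3 of 25 genes called higher, ENO2 at 1.74, PGK1 and ALDOC, but PGK1 was saturated in Cy5 on all arrays, and PGK1 was at -0.27 and ALDOC at -0.08 under median centring without loess (adjusted p = 0.0275 for the list, but adjusted p = 0.626 with an estimated correlation). The cholesterol synthesis list had SREBF1 at 1.37 and INSIG1 at 1.47 called higher and ACAT2 called lower at -1.52 (adjusted p = 0.0324, but adjusted p = 0.551 with an estimated correlation). The housekeeping reference list did not pass (adjusted p = 0.0602), but 4 of its 17 tested genes were called higher and none lower. Its median of 0.295 was close to those of the actin and keratin (0.319), glycolysis (0.329) and fatty acid oxidation (0.313) lists. Medians of that size were thus not particular to these 3 lists.

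Markers of other cell types were included because a culture can express them or be mixed. Only 8 of 26 genes of the fibroblast list and 8 of 33 of the neuron list were tested. The filter on detection let dim genes in more easily when higher under butyrate, which can favour a rise of such lists. The fibroblast and mesenchymal list had 1 of 8 genes called at 24 h, the collagen gene COL6A1 at 2.79 (adjusted p = 0.00167 for the list, and adjusted p = 0.0141 with an estimated correlation). The list's median was 0.61, 0.33 on slide 1 and 0.83 on slide 2. The neuron list had 2 of 8 called, MAPT at 1.83 and ENO2 at 1.74, and a median of 0.33, 0.46 on slide 1 and 0.19 on slide 2 (adjusted p = 0.0275, and adjusted p = 0.0372 with an estimated correlation). The estimate for the neuron list was 0, below the preset 0.01. The leukocyte list did not pass (adjusted p = 0.22). The ribosomal protein list had 7 of 47 genes called higher, with a median of 0.52 that turned to -0.78 under median centring without loess (adjusted p = 3.03e-07, but adjusted p = 0.274 with an estimated correlation). Of the 47 genes, 45 were saturated in Cy5 on 1 or more arrays, and with probes free of saturation 16 genes had a median of -0.15.

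Of 18 tested enterocyte and brush border genes at 24 h, 1 was called higher, the protocadherin gene CDHR5 at 1.35, and 1 was called lower. The list did not pass (adjusted p = 0.355). In the goblet and mucin list TFF3 at -1.77, SPDEF at -1.06 and MUC20 at -0.93 were called lower (adjusted p = 0.0378 for the list, but adjusted p = 0.0615 with an estimated correlation). The Paneth and secretory antimicrobial list passed downward with MMP7 as its 1 called gene of 5. Its median was -0.93, -0.54 on slide 1 and -0.93 on slide 2 (adjusted p = 0.00525, and adjusted p = 0.0126 with an estimated correlation of 0). REG4 at -1.17 and LCN2 at -0.93 were not called, and PIGR was above 0 at 0.59, so the list rests largely on MMP7. The enteroendocrine list had ISL1 at 1.34 and SCG5 at 1.04 called higher and did not pass (adjusted p = 0.0552).

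**Figure D1:**
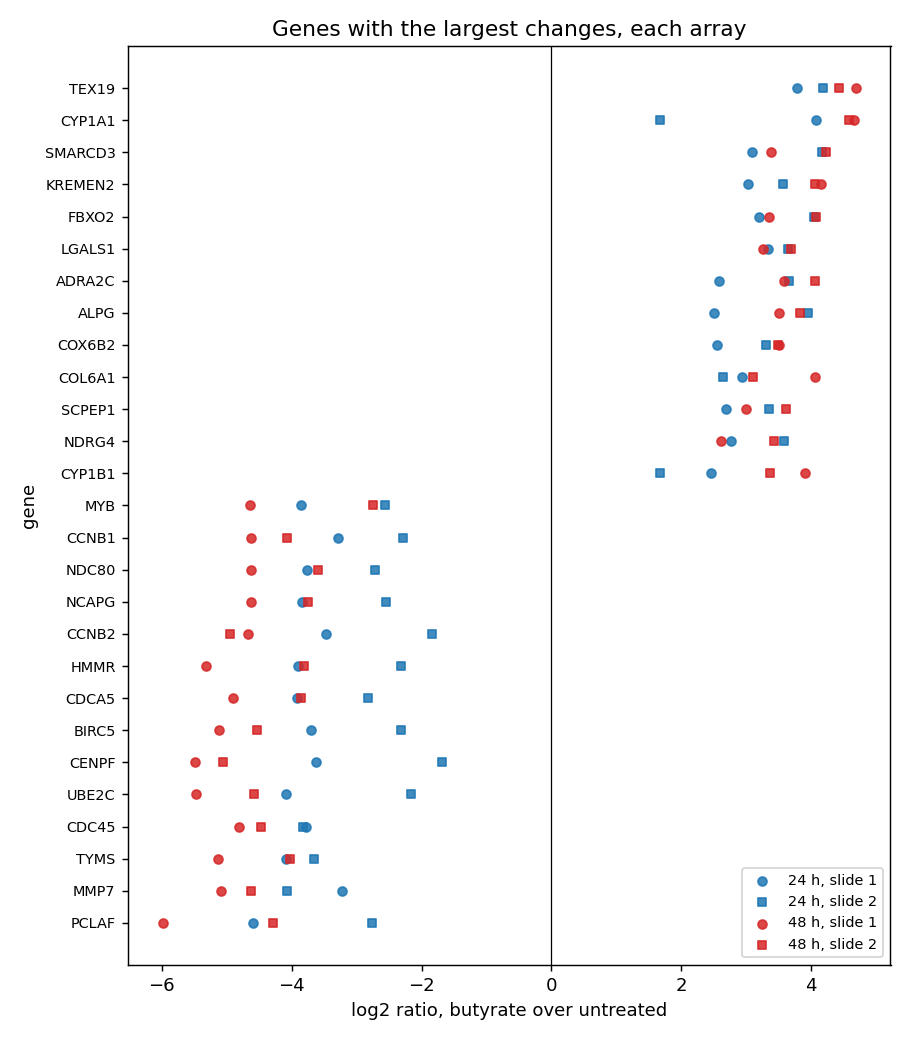
Log2 ratio of butyrate over untreated (horizontal axis) on each of the 4 arrays for the named genes with the largest rises and falls. Blue points are 24 h, red points 48 h, circles slide 1 and squares slide 2. For CENPF the 24 h arrays were at -3.62 and -1.69 and the 48 h arrays at -5.49 and -5.06.

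The second comparison asks the same after 48 h. The cell division genes were lower still by value: 56 of 57 G2/M genes and 37 of 49 G1/S genes were called lower. CENPF, a kinetochore gene, fell by 5.28 (SE 0.45, n = 2 arrays, 38.8-fold), PCLAF fell by 5.14 (SE 0.39) and BIRC5, survivin, fell by 4.83 (SE 0.33). Among genes eligible for naming, the largest rise was CYP1A1, a cytochrome of xenobiotic metabolism, at 4.62 (SE 0.59, 24.5-fold). Next were TEX19 at 4.55 (SE 0.26) and KREMEN2 at 4.10 (SE 0.26).

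At 48 h, 1021 genes were called higher and 775 lower, all with the same sign on both arrays. Of those called higher, 65 were well above background in Cy5 on no array and 245 on 1 to 3 arrays. Of those called lower, 81 were well above background in Cy3 on neither 48 h array. Without 48 h replicate 1 the counts were 617 and 372, without 48 h replicate 2 they were 1324 and 1246, and median centring without loess gave 544 and 5987. Other large rises were ADRA2C at 3.82, SMARCD3 at 3.80, FBXO2 at 3.71, ALPG at 3.66, CYP1B1 at 3.63, COL6A1 at 3.58 and COX6B2 at 3.49. Other large falls were MMP7 at -4.86, the cyclin genes CCNB2 at -4.81 and CCNB1 at -4.35, CDC45 at -4.64, TYMS at -4.58, CDCA5 at -4.38 and NDC80 at -4.11. Their adjusted p lay between 0.000187 for CDC45 and 0.000625 for CCNB2. As bounds, ASPM was at least 16.0-fold lower, ZWINT at least 12.8-fold and SPC25 at least 10.6-fold. DACT3 was at least 9.98-fold higher, RASGEF1A at least 5.24-fold and the cancer-testis antigen gene PRAME at least 3.90-fold.

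The G2/M list had a median of -2.53 at 48 h, -2.99 on slide 1 and -2.30 on slide 2 (adjusted p = 7.5e-109, and adjusted p = 2.43e-07 with an estimated correlation). The G1/S list had a median of -1.57, -1.70 on slide 1 and -1.12 on slide 2 (adjusted p = 2.53e-40, and adjusted p = 0.00496 with an estimated correlation). The xenobiotic and glutathione list had 8 of 31 genes called higher, AKR1C1 at 2.65 and TXNRD1 at 2.12 among them, and a median of 0.49 on slide 1 and 1.12 on slide 2 (adjusted p = 5.02e-06, and adjusted p = 0.00582 with an estimated correlation). The cholesterol synthesis list had 5 of 27 called higher, SREBF1 at 1.54, INSIG1 at 1.76, MVD at 1.22 and IDI1 at 1.79 among them, and a median of 1.12 on slide 1 and 0.39 on slide 2 (adjusted p = 0.000406, but adjusted p = 0.22 with an estimated correlation). Adjusted over the list alone, 12 of the 27 were higher. SREBF1 was saturated in Cy5 on 2 arrays.

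Of the colon lists at 48 h, the intestinal stem cell and Wnt target list passed downward, with DKK1 at -1.64, CDCA7 at -2.63 and ASCL2 at -1.16 called of 20 genes and a median of -0.62 on slide 1 and -0.21 on slide 2 (adjusted p = 0.0197, but adjusted p = 0.499 with an estimated correlation). The Paneth and secretory antimicrobial list passed downward with MMP7 as its 1 called gene (adjusted p = 0.0163, and adjusted p = 0.0276 with an estimated correlation of 0). Of its 5 tested genes, 3 were below 0 and 2 above. The enteroendocrine list passed upward with SCG5 at 1.82 and ISL1 at 1.92 called of 6 genes and a median of 1.18 on slide 1 and 0.20 on slide 2 (adjusted p = 0.00792, but adjusted p = 0.221 with an estimated correlation). In the enterocyte list CDHR5 at 1.95, VIL1 and the actin-bundling gene ESPN at 1.11 were called higher and 1 gene was called lower. The enterocyte list did not pass (adjusted p = 0.225). In the goblet and mucin list FCGBP was called higher at 1.73 and 4 of 18 genes lower, TFF3 at -1.96 among them, and the list did not pass (adjusted p = 0.215). In the adhesion list 3 of 22 genes were called higher, CDH17 at 2.57 and CEACAM7 at 2.11 among them, and 1 lower. The adhesion list did not pass (adjusted p = 0.362).

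The actin cytoskeleton and keratin, hypoxia and glycolysis lists did not pass at 48 h (adjusted p = 0.0966, 0.25 and 0.25), with medians of 0.32, 0.31 and 0.07. The hypoxia list's median was -0.35 on slide 1 and 0.94 on slide 2.

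The fatty acid oxidation list had 5 of 36 genes called higher and 1 lower at 48 h, ACSL1 at 2.21 and ECI2 at 1.65 among the former, and a median of 0.24 on slide 1 and 0.76 on slide 2 (adjusted p = 0.00196, but adjusted p = 0.393 with an estimated correlation). Metallothioneins had 5 of 12 genes called higher, MT2A at 1.21 and MT1F at 1.16 among them (adjusted p = 0.00358, but adjusted p = 0.205 with an estimated correlation). The ribosome biogenesis list had NOP56 at -1.10, GNL3 at -0.95 and NCL at -1.14 called lower, the last saturated in Cy5 on 3 arrays (adjusted p = 0.000225, but adjusted p = 0.509 with an estimated correlation). The ribosomal protein list passed upward at a median of 0.25 that turned to -0.84 under median centring without loess (adjusted p = 0.039, but adjusted p = 0.695 with an estimated correlation).

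In the monocarboxylate transport and receptor list 4 of 8 genes were called higher at 48 h, SLC22A2 at 1.67, ABCG2 at 1.91, BSG at 1.08 and SLC16A3 at 1.60 (adjusted p = 0.00792, but adjusted p = 0.221 with an estimated correlation). The monocarboxylate transporter gene SLC16A1 was not called, at 0.28, so the calls do not show a rise of monocarboxylate transport as such. SLC16A3 was saturated in Cy5 on 2 arrays, and its other probe gave -0.54 without saturated probes. The interferon and antigen presentation list held calls both ways, 11 higher and 5 lower of 35, with IFI6 at 1.91 and HLA-F at 1.42 against PSMB10 at -2.21 and IFITM3 at -1.45, and it did not pass (adjusted p = 0.198). The fibroblast list had COL6A1 and LUM called (adjusted p = 0.000701, and adjusted p = 0.00651 with an estimated correlation), the neuron list MAPT, ENO2 and SNCG (adjusted p = 0.00332, and adjusted p = 0.0058 with an estimated correlation), and the leukocyte list ITGAX and CD14 among its called genes without passing (adjusted p = 0.0932). All 8 tested fibroblast genes and all 8 tested neuron genes were above 0 at 48 h, which the filter on detection can favour.

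Genes fixed in advance gave the following values at 48 h. CDKN1A, the cyclin-dependent kinase inhibitor p21, rose by 1.59 (SE 0.34, adjusted p = 0.02), at 1.02 on slide 1 and 2.15 on slide 2, and without the slide block its adjusted p was 0.0733, the highest of its alternatives. Under median centring without loess it was at 0.85 (adjusted p = 0.0655). At 24 h it was at 1.16 (adjusted p = 0.0845). VIL1, villin of the brush border, rose by 1.17 (SE 0.22, adjusted p = 0.0127), but was at 0.18 under median centring without loess (adjusted p = 0.618). CDX2 was at 0.70 (adjusted p = 0.106), MYC at -0.66 (adjusted p = 0.117), or -1.61 under median centring without loess (adjusted p = 0.000789), CCND1 at 0.17 (adjusted p = 0.715), SLC16A1 at 0.28 (adjusted p = 0.536), HDAC1 at 0.29 (adjusted p = 0.467), or -0.74 under median centring without loess (adjusted p = 0.0449), and MUC2 at 0.03 (adjusted p = 0.954). Median centring does not remove a trend of the log2 ratio with brightness, and it put the median of all tested genes at -0.56 at 48 h. Its negative values for MYC and HDAC1 are therefore no separate evidence of a fall. ALPI and SLC5A8 were not well above background often enough to be tested.

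**Figure D2:**
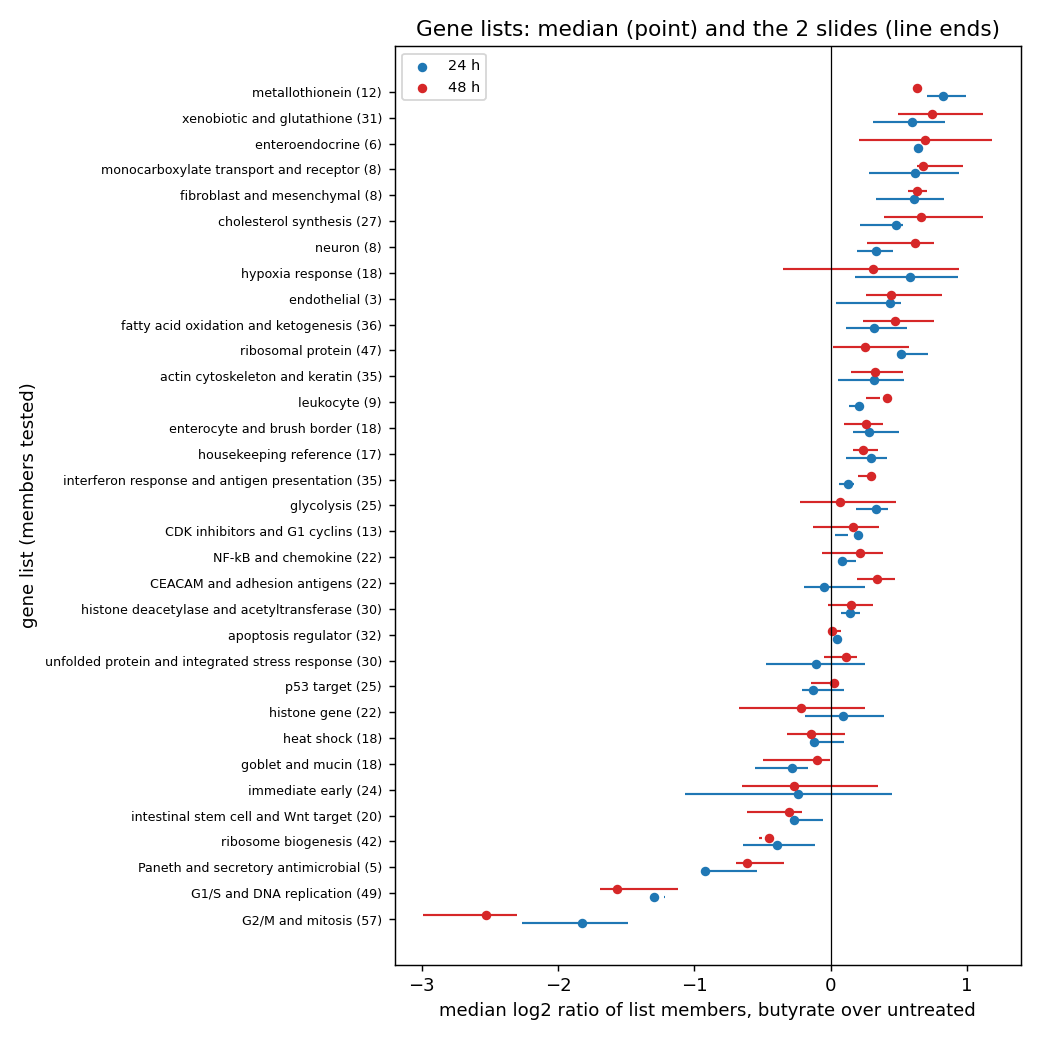
Median log2 ratio of butyrate over untreated (horizontal axis) for each tested gene list, with the number of tested members in brackets. Points are the median of the fitted values at 24 h (blue) and 48 h (red), and line ends are the medians on the 2 slides, so a point can lie outside its line. The G2/M list is lowest, at -1.82 and -2.53.

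The third comparison, 48 h versus 24 h, asks what differed between the time points. Both carried Cy3, and each slide held 1 array of either. The untreated RNA of a slide was taken to serve both, so longer butyrate and longer culture cannot be told apart here. The one gene called was PSCA, prostate stem cell antigen, which rose by 1.73 (SE 0.17, adjusted p = 0.0491), at 1.75 on slide 1 and 1.72 on slide 2. With the slide as a fixed block, which pairs the 2 arrays of a slide, PSCA was not called (adjusted p = 0.187). Nor was it called with Agilent processed signals (adjusted p = 0.125), with no filter on detection (adjusted p = 0.339) or with no replicate block. The call was also lost without 24 h replicate 1, 24 h replicate 2 or 48 h replicate 1, where the difference was 1.725, 1.74 and 1.718. Without 48 h replicate 2, 154 genes were called higher and 103 lower. With limma, 1550 genes had an unadjusted p under 0.05 against 784 by chance. That excess depended on the slide block: the number was 1408 with the slide as a fixed block and 215 with no block.

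The G2/M list was lower at 48 h than at 24 h, with a median difference of -0.76, -0.73 on slide 1 and -0.77 on slide 2 (adjusted p = 7.97e-51, and adjusted p = 0.00282 with an estimated correlation). No gene of it was called over all genes tested, and 43 of 57 were lower when adjusted over the list alone. CENPF was at -2.62, BIRC5 at -1.82 and CCNB1 at -1.57, each with adjusted p = 0.0701. The interferon list passed upward with a median of 0.22, 0.26 on slide 1 and 0.13 on slide 2 (adjusted p = 0.0109, and adjusted p = 0.00699 with an estimated correlation). The estimate for this list was 0, below the preset 0.01. None of its genes was called, also when adjusted over the list alone. The unfolded protein and integrated stress list passed upward at 0.33 with ASNS, asparagine synthetase, at -1.79 at 24 h and -0.30 at 48 h and saturated in Cy5 on 1 array (adjusted p = 1.04e-07 for the list, but adjusted p = 0.157 with an estimated correlation).

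The responses at 24 h and 48 h were compared across genes, which are not independent replicates. The correlation of log2 ratios was 0.84 and 0.91 within slides. Across slides it was 0.60 and 0.62. The 2 arrays of the same time point, also on different slides, correlated at 0.62 at 24 h and 0.66 at 48 h. The mean ratios of the time points correlated at 0.90, against 0.70 in a simulation of unchanged groups with shared controls. The simulated value follows from the within-slide correlation of 0.703 put in, which was estimated from these arrays. Their covariance was 0.349 against 0.047 simulated, a difference of 0.302. Of the genes called at 24 h, 466 were also called higher at 48 h (35 by independent lists) and 373 lower (20.7 by independent lists), and none was called in opposite directions. In 20 simulations of unchanged groups with shared controls, 0.3 genes on average were called at both. Part of the excess may come from the shared controls.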

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

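The tests of the further fall from 24 h to 48 h and of the G2/M median at 24 h, the smallest number of 5 unsaturated genes and the repeat without saturated probes were chosen after the values had been seen.

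A test of the difference between 48 h and 24 h passed for PSCA at 1.73 and, with the preset inter-gene correlation, for 12 gene lists. The G2/M list also passed with an estimated correlation. So did the interferon list, but its estimate was 0, below the preset 0.01, so that run was no stricter for it. No gene of the interferon list was called, also when adjusted over the list alone. The other 10 lists did not pass with an estimated correlation, with adjusted p = 0.0671 to 0.567. The medians upward were 0.33 for enteroendocrine, 0.19 for monocarboxylate transport and receptor, 0.36 for cholesterol synthesis and 0.22 for interferon response genes. They were 0.10 for xenobiotic and glutathione, 0.33 for unfolded protein and stress response and 0.31 for neuron genes. The medians downward were -0.24 for intestinal stem cell and Wnt target, -0.22 for G1/S, -0.76 for G2/M, -0.26 for histone and -0.26 for ribosomal protein genes.

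Genes of G2/M and mitosis were lower under butyrate, and without a dye swap a dye bias has to be weighed. A dye bias cancels between the time points, so the further difference, with a median of -0.725 on the slide where it was weaker, argues against the dye for that part. For the fall at 24 h, 11 other probes of called members had a median of -0.895 and all were below 0, which is short of the -1 set beforehand as evidence against a bias of single probes. A bias shared by whole transcripts cannot be told apart from the treatment at the list's median of -1.825, since no array swapped the dyes. An effect of butyrate on dividing cells stays open, as does a difference in serum between treated and untreated cells, which was not tested. The further fall from 24 h to 48 h also cannot be told apart from longer culture. The time points of a slide were taken to share 1 untreated RNA, so no control was matched in time.

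Log2 ratios differed between the slides. If the high Cy5 background of slide 1 were the cause, bright genes would be spared, but in the brightest 3919 genes the slide differences of 24 h and 48 h correlated at 0.763. That argues against the background as the whole cause. A difference between the untreated RNA samples or their Cy5 labelling predicts more variance between slides in Cy5 than in Cy3, and the ratio was 1.294, between the bounds set beforehand. The untreated RNA, the cultures and the hybridisation cannot be told apart by that value.

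The ribosomal protein list passed upward at 24 h with 7 of 47 genes called and 45 saturated in Cy5 on 1 or more arrays, but not with an estimated correlation (adjusted p = 0.274), and its median was -0.779 under median centring without loess. The 2 members saturated on no array had a median of -0.174, below the 0.1 set beforehand for saturation, but 2 genes were held too few to decide by the minimum of 5 set afterwards. With other probes allowed, the 16 genes with unsaturated probes had a median of -0.15, with 10 of them below 0. The list's median lay at percentile 94.36 of 10000 random lists matched on brightness, under the 95 set beforehand for a trend with brightness, but close to that limit. The random lists could draw the list's own genes, which can lower the percentile, and they were not matched on saturation. A trend with brightness therefore stays open and is not decided by that value. An effect of butyrate on the ribosomal protein genes was not separately tested.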

How the results depend on the processing

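The repeat without probes saturated in Cy5 was chosen after seeing the data. The cause of a change was not tested unless given. The G2/M list kept its direction and its side of the threshold in all 3 comparisons under every alternative run, with medians from -2.82 to -1.71 at 24 h, -4.03 to -2.35 at 48 h and -1.38 to -0.51 between them. A change of sign where neither value passed was not counted as a reversal. Loess followed by Aquantile leaves log2 ratios unchanged by construction and tests nothing. Low signal over background limits dim genes, above all in Cy5 on slide 1.

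Median centring without loess does not remove a trend of the log2 ratio with brightness. Higher calls went from 56.3% to 4.7% of calls at 24 h and from 56.8% to 8.3% at 48 h. The centring moved the median of all genes to -0.658 at 24 h and -0.562 at 48 h. It called 345 genes higher and 7021 lower at 24 h, 544 and 5987 at 48 h, and 28 and 9 between them, with 5 lists higher at 24 h. Among the lists and genes reported here or taken by the naming rule, values above 0 turned negative at 24 h for the ribosomal protein list (-0.779), CDH1 (-0.195), PGK1 (-0.27), ALDOC (-0.076), MT1B (-0.017), ANXA1 (-0.005), RPS18 (-0.285), EEF1A1 (-0.106), RPL11 (-0.116), RPL19 (-0.179) and HDAC1 (-0.918). At 48 h they turned for the ribosomal protein list (-0.835), CDH1 (-0.166), PDIA4 (-0.067), RPL27 (-0.022), RPL11 (-0.198) and HDAC1 (-0.736). The mean correlation across slides between 24 h and 48 h was 0.61, and 0.661 with this centring and 0.631 with Agilent processed signals.

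Without background correction 861 genes were called higher and 700 lower at 24 h, and 10 and 2 between the time points. Agilent processed signals gave 6 lists higher at 24 h, 473 genes lower at 48 h and 0 genes higher between the time points. With no filter on detection 0 genes were called higher between the time points and 4 lists passed upward. With both channels well above background on all arrays, where fewer genes are tested, 5 genes were higher and 4 lower between the time points and 3 lists passed downward. A trended and robust variance gave 15 and 5 genes. With no replicate block 0 genes were higher between the time points and 3 lists passed downward. With the slide as a fixed replicate block 0 genes were higher, and 1408 had an unadjusted p under 0.05 in limma. Against untreated cells that block takes slide 1 as its base and leaves out the spread between slides, so its 4277 calls at 24 h and 5525 at 48 h are for slide 1 and not the main comparison. With an estimated inter-gene correlation 4 lists passed upward and 3 downward at 24 h, 3 and 3 at 48 h, and 1 and 1 between the time points. Without saturated probes the ribosomal protein list was at -0.149 at 24 h and -0.413 at 48 h, and SLC16A3 at 48 h was at -0.536.

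Leaving out each array in turn, with a lone array assumed to vary like the others, gave 126 to 895 genes higher and 127 to 771 lower at 24 h, 617 to 1324 and 372 to 1246 at 48 h, and 1 to 154 and 1 to 103 between the time points. The lowest counts at 24 h came without 24 h replicate 2 and the highest counts between the time points without 48 h replicate 2. Lists passing were 9 to 12 upward and 4 to 7 downward at 24 h, 6 to 12 and 5 to 6 at 48 h, and 4 to 9 and 4 to 7 between the time points. Between the time points the ribosome biogenesis list ranged from -0.342 to 0.157 and the immediate early list from -0.338 to 0.58, and both turned without 24 h replicate 1.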

Other observations

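The 5 gene groups in this part were chosen after the results had been seen, and their tests describe these arrays only. Lysosomal genes were higher: 11 of 37 were called higher at 24 h (median 0.50, adjusted p = 3.06e-10) and 17 of 37 at 48 h (median 0.78, adjusted p = 6.97e-13), with none lower. With an estimated correlation the adjusted p was 1.58e-05 and 6.13e-07. The median was 0.51 and 0.56 on the slides at 24 h and 0.76 and 0.73 at 48 h.

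Genes of Fanconi and homologous recombination repair were lower, with 10 of 25 called at 24 h (median -0.97, adjusted p = 3.1e-17) and 14 of 25 at 48 h (median -1.31, adjusted p = 2e-18). With an estimated correlation the adjusted p was 0.00372 and 0.0025. Proteasome genes had medians of -0.05 at 24 h and -0.17 at 48 h (adjusted p = 0.912 and 0.691), and respiratory chain genes -0.11 and -0.03 (adjusted p = 0.212 and 0.691), with no gene called in either group. Cytosolic tRNA synthetases had a median of -0.18 at 24 h (adjusted p = 0.0449, but adjusted p = 0.102 with an estimated correlation). At 48 h their median was -0.07 with 1 gene called higher (adjusted p = 0.691), and for 48 h versus 24 h it was 0.21 (adjusted p = 0.0102, but adjusted p = 0.0509 with an estimated correlation).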
